A study of Arabidopsis thaliana with 12 samples.

How the data were processed

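Total RNA of 12 samples, 6 WT and 6 prors2, was measured on 1-channel arrays, and the replicate numbers 1 to 6 were taken from the labels. The deposited table gives a relative intensity per feature and sample on a linear scale. No value lies below 0, many are exactly 0, and several features of each array share an upper limit of 100. What the authors divided the intensity by, the background correction, the array type and the software are not given in the sources used here. The table held 3439 features and 0 value columns of other samples. No pair of columns was identical.

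The array medians and sums differed by more than the limit of 5% set beforehand, so log2 values, with zeros as missing, were quantile-normalized between arrays. Zeros are more frequent in WT, so leaving them out drops the dimmest values of that group more often. A feature was tested if at least 4 of 6 values per group were above 0, which held for 3024; 2654 of them had a value in all 12 samples. Differences (prors2 minus WT) were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the one term, two-sided, and adjusted by Benjamini and Hochberg over all tested features, threshold 0.05. Folds of features with missing values use the samples above 0. Single values per array were compared with two-sided exact permutation tests.

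The platform's gene table, dated by its own header and possibly old, gave 692 probes with 1 gene and 870 with several, while 1877 features were not in it and stay unnamed here. Only single-gene probes were named; 690 of 692 matched the TAIR10.1 reference gene table, which gave the symbols. No build is named for the array, so no coordinates are printed. AT2G25870 had a pair of single-gene probes, kept apart; neither changed.

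Choices made before the data were examined were the test, the scaling rule, 22 gene lists of 355 loci, their light-reaction union, and the rule for named genes. That rule takes the targeted genes, the 12 largest rises and 12 largest falls past the threshold whose 6 prors2 values lie on one side of the WT mean, and up to 3 members per list with the smallest adjusted p, or the member with the smallest p where none passed. For AT5G55580, named through its list, 5 prors2 values were above 0. A gene outside that rule is named only as a list member described in a group or, in the closing section, where said. Of the 355 loci 18 had a single-gene probe and 15 were tested, 3 higher, 7 lower and 5 not past. The other 14 lists had 0 tested members: electron transport and ATP synthase, plastid chaperones and proteases, plastid protein import, starch, plastid isoprenoids and carotenoids, photorespiration, nitrogen and sulfur assimilation, plastid fatty acids, proline, plastid transcription, mitochondrial stress, senescence, seed storage and cytosolic housekeeping. So markers of another tissue and control genes are not analysed here. No member was dropped.

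A further 6 lists were written from the names of single-gene probes after the platform table was read. That was before any test, but after values of the brightest and a few random features had been seen without gene names. Lists with at least 5 complete members were tested with camera (preset correlation 0.01, and an estimated one) and adjusted over the 6 lists so tested. Camera needs complete values, so it ran on the 2654 complete features, a subset of those in the fit. Fry was run as an alternative: it asks whether a list's genes move one way on balance, not whether they differ from other genes.

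Whether replicate numbers pair the samples was checked from deviations from the group means over the 2654 complete features. Same-numbered WT and prors2 samples correlated between 0.212 and 0.399, and 12 of 12 samples correlated best with their own number, so the numbers pair the samples by the rule set beforehand, as seen in the data and not stated in the labels. With the number as a block, 1605 features were called. Samples of replicates 1 and 2, 3 and 4, and 5 and 6 also deviated together (mean correlation 0.117 within and -0.104 between these sets, over samples of opposite genotype and other number). The direction within each of the 3 sets was therefore counted over the called and the named features, and values within the sets are given for the light-reaction list, 4 of its genes and some genes in which they were uneven.

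The alternatives were the replicate block, other scalings, other treatments of 0 (an offset of 0.0218, or the lowest positive value), a filter on the dimmest 25%, trend and robust fits, array weights, a per-gene exact permutation test, a 1.5-fold minimum, and leaving out each sample. Zeros kept with an offset, the 3 sets as a block and the sets averaged were chosen after seeing the data. The fit was tested on simulated data of 3024 features with 200 changed: it recovered 17% of those changed by 0.5 and 55% of those changed by 1 on the log2 scale, with 2 false calls among 74. The blocked fit recovered 12% and 62%, with 4 false among 78. The permutation test recovered 0 in that setting. The data held far more calls, 1427 in limma and 1399 in the permutation test, and the simulation had no sets of neighbouring numbers. The recovery rates describe the simulated setting and not these data.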

Results

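Transcript levels were compared between Arabidopsis thaliana plants of the prors2 line and wild-type (WT) plants, both in the Columbia 0 background. The labels describe prors2 as a mutant without prolyl-tRNA synthetase, the enzyme that loads proline onto its tRNA. Each of 12 arrays carried total RNA of 1 sample, 6 WT and 6 prors2, and the table held 3439 features. Tissue, age and growth conditions are not given in the sources used here. The labels do not say that the samples came from separate plants, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

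The deposited relative intensities run from 0 to 100, and what they are relative to is not given in the sources used here. The median feature stood at 0.154 ± 0.014 (SD, n = 6) in WT and at 0.292 ± 0.0099 in prors2 (two-sided exact permutation test, p = 0.00216, the smallest that 6 against 6 samples can give). An array had 382 ± 10 features at 0 in WT and 289 ± 20 in prors2, with the same exact permutation p of 0.00216. A fixed set of 20 features, the brightest by their mean over all 12 arrays, carried 37.4% ± 1.4 of the summed intensity of a WT array. In prors2 the same set carried 29.9% ± 0.67 (exact permutation p = 0.00216). The sums themselves differed less, at 3031 ± 97 and 3188 ± 72 (exact permutation p = 0.0216). Benjamini-Hochberg adjustment over the 8 measures compared gave 0.00289 for the first 3 and 0.0247 for the sums. These tests shuffled the 12 samples freely and ignored the pairing by replicate number seen in the data. Tests that keep the pairs or the sets of neighbouring numbers have fewer arrangements, cannot reach p-values this small, and were not run on these measures. The median log2 difference over the tested features was 0.76 on the deposited values, 0.69 at equal sums, 0.07 after quantile normalization and -0.06 after median centring. Directions and sizes below are those after quantile normalization unless another scaling is named. The list counts below are to be read against the array as a whole. Of the 3024 tested features 47.2% were called after quantile normalization, 751 higher and 676 lower. The deposited values gave 1747 higher and 269 lower, equal sums 1664 and 298, and median centring 600 and 881. Another scaling moved the log2 size of 30 of the 44 genes named by the rule by over 1.5 times or turned its sign.

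**Figure D1:**
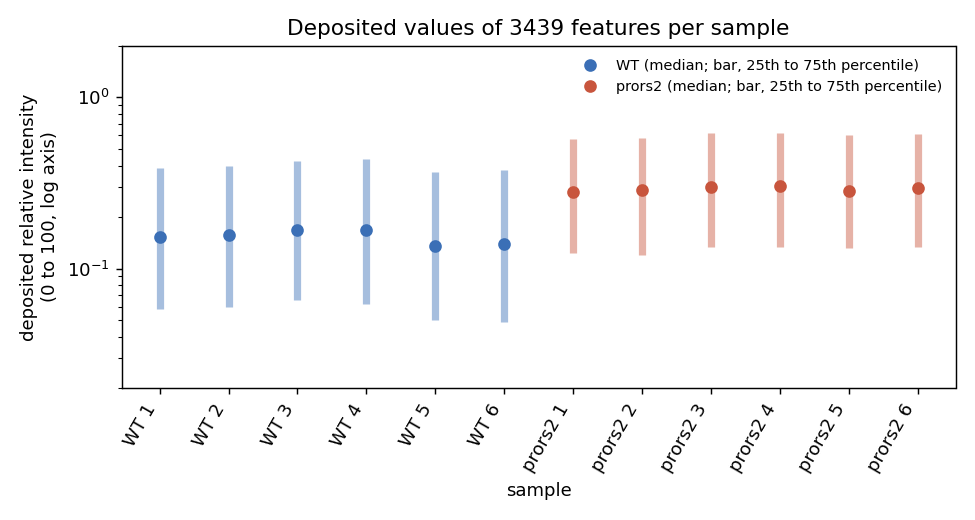
Deposited relative intensity of the 3439 features in each of the 12 samples, on a log axis. Points are the median and bars run from the 25th to the 75th percentile. The WT medians lie between 0.135 and 0.169 and the prors2 medians between 0.279 and 0.305.

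The prolyl-tRNA synthetase genes were looked for first. No probe that the platform table ties to AT5G52520 (the organellar enzyme) or AT3G62120 (the cytosolic one) was found, alone or with other genes, so the targeted gene is not analysed here and the genotype labels have no check at the transcript level.

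Of 5 tested nuclear genes for the photosynthetic light reactions, 3 fell in prors2. LHB1B2 (AT2G34420), a chlorophyll a/b-binding protein of the photosystem II antenna, stood at a relative intensity of 32.7 ± 2.0 (SD, n = 6) in WT and 10.6 ± 0.36 in prors2. PSAN (AT5G64040), a photosystem I subunit on the lumen side, went from 9.04 ± 0.81 to 3.31 ± 0.39. PSBY (AT1G67740), a small photosystem II subunit, went from 7.89 ± 0.98 to 2.97 ± 0.42. After normalization their log2 differences were -1.23 (SE 0.076, limma adjusted p = 1.75e-07), -1.24 (SE 0.12, adjusted p = 4.92e-06) and -1.22 (SE 0.14, adjusted p = 2.88e-05). All 3 were called lower under each of the 4 scalings, and the falls were larger after median centring, at -2.46, -2.28 and -2.24. Within the sets of replicates 1 and 2, 3 and 4, and 5 and 6, LHB1B2 lay at -1.12, -1.28 and -1.31, PSAN at -1.30, -1.36 and -1.07, and PSBY at -1.42, -1.30 and -0.94. LHB1B2 belongs to a family of near-identical genes, so its probe may also read its relatives.

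Of the 61 loci listed for the light reactions, 5 were tested through a single-gene probe. Of these 1 rose, 3 fell and 1 did not pass, with the same counts when adjusted over the list alone. The riser was PSB27 (AT1G03600), a lumen protein of photosystem II assembly and repair, at a log2 difference of 0.62 (SE 0.15, limma adjusted p = 0.00483); median centring turned it to -0.19. Within the 3 sets PSB27 lay at 1.05, 0.53 and 0.27. PSBW (AT2G30570), another photosystem II subunit, stood at 34.6 ± 11.6 in WT and 40.4 ± 13.0 in prors2 (SD, n = 6), a log2 difference of 0.51 (SE 0.27, limma adjusted p = 0.143), which was -0.59 after median centring. With replicate numbers as a block, PSBW passed (limma adjusted p = 0.00192). The list as a whole did not stand apart from the other features (camera adjusted p = 0.161; adjusted p = 0.219 with an estimated correlation), and lay at -0.45, -0.61 and -0.57 relative to them within the 3 sets. On the deposited values, at equal sums and after median centring it did, with camera adjusted p of 8.81e-04, 0.00155 and 0.0237.

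**Figure D2:**
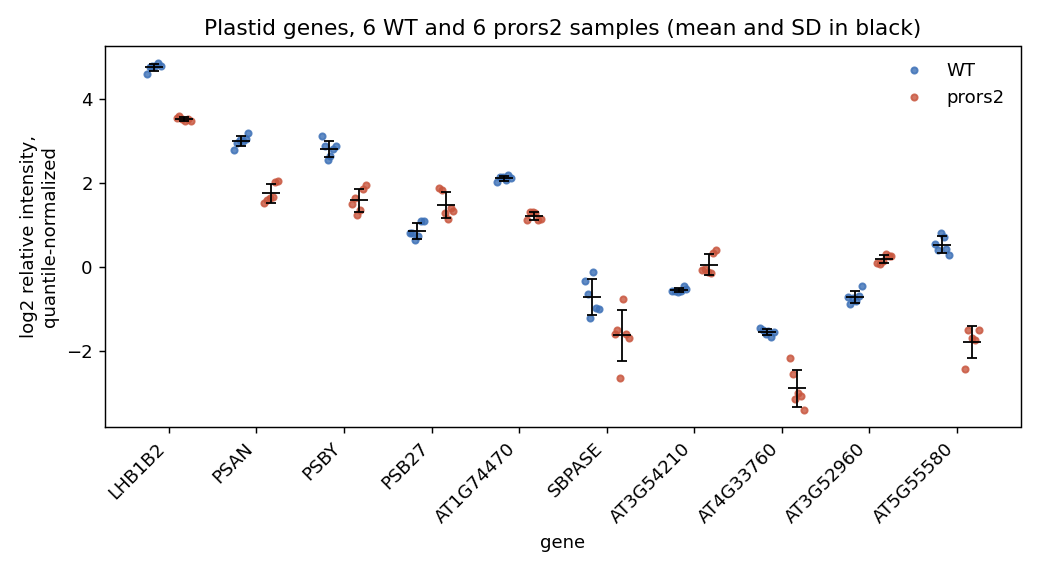
Quantile-normalized log2 relative intensity of 10 genes of plastid or organellar function in the 6 WT and 6 prors2 samples. Each point is a sample, and black marks give the mean and SD. LHB1B2, PSAN, PSBY, AT1G74470, AT4G33760 and AT5G55580 are lower and AT3G52960 is higher in prors2 under all 4 scalings. PSB27 and AT3G54210 are not called after median centring, where PSB27 is at -0.19, and SBPASE is not called on the deposited values or at equal sums.

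Both measured genes of tetrapyrrole synthesis were called lower, 1 of them under all 4 scalings. AT1G74470, the geranylgeranyl reductase that makes the phytyl tail of chlorophyll, differed by -0.90 (SE 0.080, limma adjusted p = 2.90e-06), and its deposited value went from 4.57 ± 0.22 to 2.34 ± 0.20 (SD, n = 6). CHLM (AT4G25080), a methyltransferase of chlorophyll synthesis, differed by -0.55 (SE 0.12, limma adjusted p = 0.00247). It was not called on the deposited values or at equal sums, where its log2 differences were 0.06 and -0.01. In the Calvin cycle list, SBPASE (AT3G55800), sedoheptulose-bisphosphatase, fell by 0.91 (SE 0.28, limma adjusted p = 0.0186). That call was lost on the deposited values and at equal sums, with log2 differences of -0.31 and -0.38. PRK (AT1G32060), phosphoribulokinase, differed by -0.02 (SE 0.11, limma adjusted p = 0.918), but by -0.83 after median centring, where it was called lower. Adjusted over the list alone, the counts were the same in both lists, 2 lower of 2 and 1 lower of 2.

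Genes of organellar translation did not move one way. AT4G33760, an aspartyl-tRNA synthetase, fell by 1.34 (SE 0.18, limma adjusted p = 8.55e-05) and was the only measured member of the list of organellar aminoacyl-tRNA synthetases and translation factors. On the deposited values and at equal sums AT4G33760 was also called lower, at -0.51 and -0.58. Of 4 tested plastid ribosomal protein genes, 1 passed, also when adjusted over the list alone. AT3G54210 (ribosomal protein L17) rose by 0.61 (SE 0.12, limma adjusted p = 9.83e-04), a call lost after median centring (0.13). AT1G64510, AT3G13120 and AT4G01310 had log2 differences of -0.77, -0.31 and -0.25 (limma adjusted p = 0.124, 0.384 and 0.321), which turned to 0.16, 0.34 and 0.40 on the deposited values and to 0.09, 0.27 and 0.33 at equal sums.

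Among antioxidant enzymes, AT3G52960, a plastid type II peroxiredoxin, rose by 0.90 (SE 0.095, limma adjusted p = 1.19e-05), and by 0.44 after median centring. It was the only measured member of the fixed list. Another list of redox genes was written after the platform table had been read. Of its 7 tested members 2 rose, 4 fell and 1 did not pass, as also when adjusted over the list alone. The 2 risers were AT3G52960, which stands in both lists, and CCS. GLDH (AT3G47930), the last enzyme of ascorbate synthesis, fell by 1.11 (SE 0.11, limma adjusted p = 9.15e-06). It was called lower under all 4 scalings, at -0.44 on the deposited values and -0.51 at equal sums. NTRC (AT2G41680), a plastid thioredoxin reductase, fell by 0.94 (SE 0.14, limma adjusted p = 2.07e-04), but not past the threshold on the deposited values or at equal sums. On those scalings 2 members were higher and 1 lower. CCS (AT1G12520), the copper chaperone of superoxide dismutase, rose by 1.34 (SE 0.51, limma adjusted p = 0.0484), but not with replicate numbers as a block (limma adjusted p = 0.0790). Within the 3 sets CCS ran from 0.094 to 2.16. Over its 5 complete members, without CCS, the list did not stand apart (camera adjusted p = 0.161, and 0.219 with an estimated correlation).

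Pentatricopeptide repeat and mTERF proteins, which mostly bind organellar nucleic acids, formed the largest added list. Of 25 tested members 10 rose, 2 fell and 13 did not pass, with the same counts when adjusted over the list alone. AT1G31790 and AT3G18870 rose by 1.23 (SE 0.089, limma adjusted p = 5.32e-07) and 0.93 (SE 0.12, limma adjusted p = 4.19e-05). AT5G55580 (mTERF9) was 4.94-fold lower (SE 0.18 on the log2 scale, limma adjusted p = 1.85e-06) over the 5 prors2 samples above 0. With zeros at the lowest positive value AT5G55580 differed by -4.96 and did not pass (limma adjusted p = 0.148). AT5G15280 differed by 0.72 (limma adjusted p = 0.274) and passed with replicate numbers as a block, at 0.85 (limma adjusted p = 0.00444). Requiring all 4 scalings favours higher calls, since the deposited values and equal sums carry an upward shift. Under all 4 scalings 9 members were called higher and 1 lower, while the counts alone ran from 9 higher and 3 lower after median centring to 21 higher and 1 lower on the deposited values. Over its 18 complete members, AT5G55580 and AT1G79080 not among them, the list did not stand apart from the other features (camera adjusted p = 0.139, and 0.219 with an estimated correlation). A comparison chosen after these counts were seen set its 10 higher and 2 lower calls against 146 higher and 117 lower among the other single-gene features, and did not pass (two-sided Fisher's exact test, p = 0.0745).

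Of 9 tested genes for thylakoid biogenesis and assembly, 1 rose, 3 fell and 5 did not pass; adjusted over the list alone, 2 rose and 3 fell. ATAB2 (AT3G08010), a translation factor for photosystem subunits, fell by 1.59 (SE 0.40), LPA19 (AT1G05385), a photosystem II assembly factor, by 0.78 (SE 0.20) and SECE1 (AT4G14870), a thylakoid protein translocase subunit, by 0.44 (SE 0.10). Their limma adjusted p were 0.00576, 0.00656 and 0.00386. None of the 3 was called on the deposited values or at equal sums, where LPA19 and SECE1 lay slightly above 0. On those 2 scalings 5 members were higher and 0 lower. The list's median difference was 0.14 and its mean -0.18 (camera adjusted p = 0.707, direction down; adjusted p = 0.761 with an estimated correlation).

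OTP85 and CRR21 stood in both the pentatricopeptide repeat list and the list for the chloroplast NADH dehydrogenase-like complex and its expression factors. In the latter list 0 of 6 tested members passed in limma, 0 had an unadjusted p under 0.05, and the per-gene exact permutation test called 0. On the deposited values 4 were called higher, and after median centring 2 lower. NdhN (AT5G58260), the member with the smallest p, differed by 0.26 (SE 0.13, limma adjusted p = 0.141); without prors2 replicate 2 it passed at 0.35 (limma adjusted p = 0.0271). Of 7 tested histone H3, kinesin and FBL17 genes, AT4G14330 rose by 0.66 (SE 0.12, limma adjusted p = 6.56e-04). AT3G44050, a kinesin, fell by 0.95 (SE 0.34, limma adjusted p = 0.0435). That call was lost with replicate numbers as a block (at -0.93, limma adjusted p = 0.0649), when adjusted over the list alone and under the other 3 scalings. It was also lost in the per-gene exact permutation test and with zeros at the lowest positive value (limma adjusted p = 0.0880). FBL17 differed by -0.65 (SE 0.53, limma adjusted p = 0.350) and by 0.38 on the deposited values. With replicate numbers as a block FBL17 passed, at -0.99 (limma adjusted p = 0.0146). On the deposited values and at equal sums 5 of the 7 were called higher and 0 lower, and after median centring 1 higher and 0 lower. Over the 5 complete members of each, neither list stood apart (camera adjusted p = 0.820 and 0.707, and 0.852 and 0.761 with an estimated correlation). Of 4 tested mitochondrial respiration genes 1 passed, also when adjusted over the list alone. AT5G47030, a subunit of the mitochondrial ATP synthase, fell by 1.68 (SE 0.40, limma adjusted p = 0.00403), but not past the threshold on the deposited values or at equal sums. On each of those 2 scalings 3 members of the respiration list were called higher and 0 lower.

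The 12 largest rises among single-gene features ran from 1.72 to 3.51 on the log2 scale, and all 12 were called higher under the 4 scalings. With zeros at the lowest positive value AT3G14890, GH9B16, AT4G03150 and AT1G79080 did not pass (limma adjusted p = 0.149, 0.101, 0.107 and 0.214). AT3G15140 had the largest, at 3.51 (SE 0.28, limma adjusted p = 4.51e-06), from a deposited 0.012 ± 0.013 (SD, n = 6) to 0.346 ± 0.045. Of its 6 WT samples 2 were at 0 and left out, and its size depends on how they are treated. It was 2.61 with an offset before log2 and 7.23 with zeros at the lowest positive value. AT4G31930 rose by 2.49 (SE 0.16), AT3G09080 by 2.27 (SE 0.13), AT3G14890 by 2.23 (SE 0.24) and AT1G73470 by 2.07 (SE 0.14). AT4G35660 was the brightest of them, at 2.95 ± 0.46 in WT and 13.6 ± 2.3 in prors2, a log2 difference of 2.38 (SE 0.15, limma adjusted p = 2.11e-07). The others were GH9B16 (AT4G38990), a glycosyl hydrolase, AT4G03150, PRA1.B6 (AT5G07110), AT5G40050, AT1G79080 and AT5G22340, which lay at 2.97, 1.16 and 1.02 within the 3 sets. At least 1 WT sample was at 0 and entered as missing in 5 of the 12.

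The 12 largest falls ran from -1.59 to -2.50, and 7 of them were called lower under all 4 scalings. The upward shift on the deposited values and at equal sums makes such calls harder to reach for falls than for rises. AT1G21500 had the largest, at -2.50 (SE 0.14, limma adjusted p = 8.74e-08), from a deposited 0.933 ± 0.090 (SD, n = 6) to 0.253 ± 0.042. AT1G68660, the ClpS1 adaptor of the plastid Clp protease, fell by 1.81 (SE 0.093, limma adjusted p = 5.52e-08), from 1.61 ± 0.067 to 0.588 ± 0.055. AT3G52070 fell by 2.06 (SE 0.21), AT2G21530 by 1.91 (SE 0.18), AT1G11800 by 1.87 (SE 0.16), AT5G06990 by 1.86 (SE 0.13) and AT1G51350 by 1.71 (SE 0.11). AT2G01400, AT5G56070, AT3G56290, AT5G47030 and ATAB2 were not called on the deposited values or at equal sums. With zeros at the lowest positive value AT2G01400, AT3G56290 and AT5G47030 did not pass (limma adjusted p = 0.0631, 0.138 and 0.0626). AT5G56070 lay at -3.42, -0.84 and -0.91 within the 3 sets, and AT2G01400 at -2.46, -2.85 and -1.01.

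**Figure D3:**
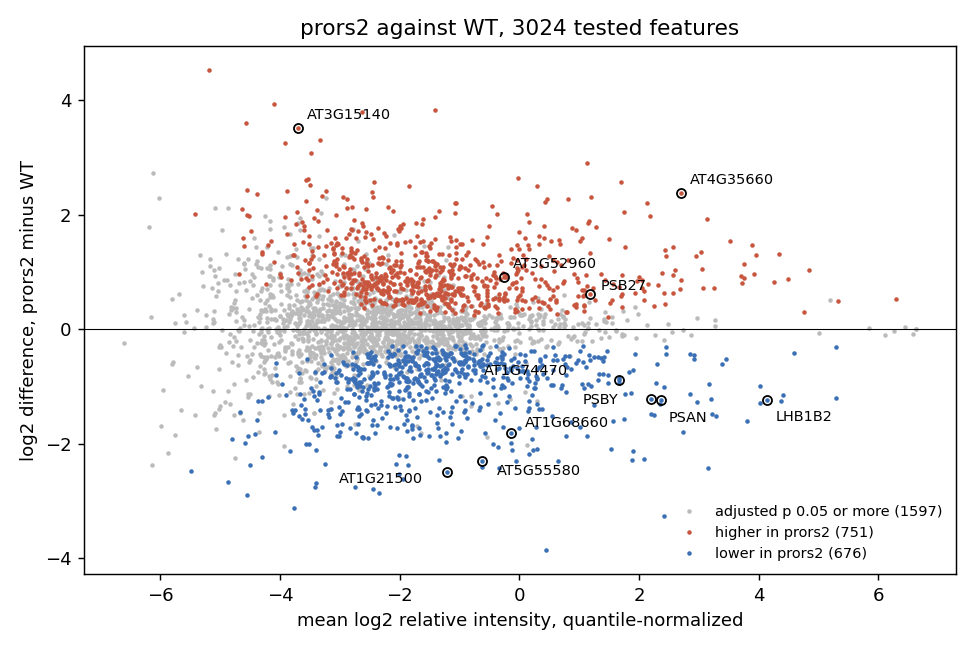
Log2 difference (prors2 minus WT) against mean quantile-normalized log2 relative intensity for the 3024 tested features. Red and blue points are the 751 higher and 676 lower features at an adjusted p under 0.05, and grey points the rest. On the deposited values the same test calls 1747 higher and 269 lower, and after median centring 600 higher and 881 lower. PSB27, circled among the higher features, lies at -0.19 after median centring.

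Across the array, limma called 1427 of 3024 tested features (47.2%), 751 higher and 676 lower in prors2. Among 606 tested single-gene features, 156 were higher and 119 lower. A change of at least 1.5-fold was seen in 1123 of the called features and of at least 2-fold in 582. In 1392 of the 1427 the difference had the same direction in all 3 sets of neighbouring replicate numbers, as it had in all 44 genes named by the rule. Nearly all of these were chosen by their difference in the same 12 samples, so that agreement was largely built in. It was not counted over all tested features. The groups did not overlap at all in 940 of the 3024 tested features, where chance gives 0.216% of features with all values. The split of directions depended on the scaling. It was 1747 higher and 269 lower on the deposited values, 1664 and 298 at equal sums, and 600 and 881 after median centring. Under all 4 scalings, 556 features were called higher and 263 lower, of which 115 and 34 were single-gene features. Requiring all 4 favours higher calls, because the deposited values and equal sums left median log2 differences of 0.76 and 0.69. The excess of higher features in that count is therefore not independent of the scaling.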

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

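The tests on the deposited scale and on the sets of replicate numbers were chosen after those patterns were seen; the comparison with other splits of the samples was planned.

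In 10 of 96 groups of values checked, 1 sample stood further from the rest than Dixon's limit allows, where chance gives about 1 in 20, or 4.8. Of the 10, 5 are prors2 replicate 1 as the lowest sample above 0. Its gap took 0.714 of the prors2 range in AT3G15140, 0.676 in AT3G56290, 0.643 in AT1G11800, 0.746 in AT5G55580 (over 5 samples, replicate 2 being at 0 and left out) and 0.683 in AT1G21500. WT replicate 1 was lowest in LHB1B2 (0.691 of the WT range; 29.4 against 32.7 for the next sample) and in AT3G56290 (0.636). In NTRC, WT replicate 5 (0.750) and prors2 replicate 3 (0.736) were lowest. In AT5G22340, prors2 replicate 2 was highest (0.803), at a deposited 1.35 against 0.343 for the next. These calls held without any 1 sample, the number of called features staying between 1343 and 1397.

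The number of changed features was set against other splits of the 12 samples. Of 100 splits into 6 and 6 drawn from 462, only 1, the real one, gave as many as its 1427 features, and the highest other gave 0. Among the 32 splits that part every pair of the same number, again 1, the real one, gave as many, and the highest other gave 0. Chance labelling of the 12 arrays as separate units does not account for this count. The arrays pair by number and deviate together by set, and the labels do not say that they came from separate plants. The splits therefore cannot address chance differences between plants. Whether the genotype or another difference between the groups lies behind the count was not tested.

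On the deposited scale dim features were higher in prors2, and bright ones less so. The median log2 difference was 1.11 in the dimmest 25% of features and 0.32 in the brightest 25%, a gap of 0.794 (0.585 to 1.04 over the 6 same-numbered pairs), which 1 scaling factor per array would leave near 0. A constant background would add the same linear amount everywhere, but the median linear difference in the next-to-brightest 25% was 3.06 times that in the dimmest 25% (2.60 to 3.02 over the pairs, each with its own medians). A few bright features taking most of the signal would leave no difference once the 50 brightest were left out of the sums; it stayed at 0.422 (0.345 to 0.466 over the pairs), against 0.69 at equal sums over all features, so they may account for part. A non-linear response of the arrays, the authors' scaling and a genotype effect on many transcripts stay open, untested.

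Samples of neighbouring replicate numbers deviated together. Over samples of opposite genotype and different number, the mean correlation of deviations was 0.221 higher within the sets 1 and 2, 3 and 4, and 5 and 6 than between them, against 0.143 for the highest of the other ways to form 3 such sets, 15 in all. This is consistent with shared runs, which the labels do not record; shared growth or RNA preparation was not tested. Each set holds both genotypes, so such runs cannot by themselves make the difference between prors2 and WT.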

How the results depend on the processing

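The tests with zeros kept, with the 3 sets as a block and with the sets averaged were chosen after seeing the data; the others were planned. The number of changed features stayed within 1.5 times of 1427 under every alternative run, from 1123 with a 1.5-fold minimum to 2016 on the deposited values; of the latter 1011 were the same features in the same direction and 31 turned. With replicate numbers as a block it was 1605, 1385 of them shared with the 1427; the block changed the calls of PSBW, CCS, AT3G44050, FBL17 and AT5G15280, given with those genes, and no other call of a named gene, list member or list. With sets averaged FBL17 did not pass. Averaging the sets gave 1182, and leaving out 1 sample 1343 to 1397. The share of calls that were higher, 52.6%, moved to 86.7% on the deposited values and 84.8% at equal sums, and turned to 40.5% after median centring, 49.9% with zeros at the lowest positive value and 49.0% with zeros kept; leaving out 1 sample gave 51.1% to 54.1%. The scalings differ by construction in the shift they leave between groups; for the zeros the cause was not tested. The light-reaction list lay at -0.54 relative to all complete features and did not pass. It passed at -1.41 on the deposited values, at equal sums and after median centring (camera adjusted p = 8.81e-04 to 0.0237). Those 3 scalings share that 1 difference, so they are not separate results. The list stayed at -0.57 to -0.53 without any 1 sample. Fry, which tests a list against no change and not against other features, passed the light-reaction (adjusted p = 1.34e-09), pentatricopeptide repeat (9.87e-07), redox (4.76e-05) and histone and kinesin (0.0221) lists. Leaving out 1 sample gave 0.26 to 0.48 for the pentatricopeptide repeat, -0.74 to -0.36 for the redox, -0.25 to -0.16 for the thylakoid and 0.025 to 0.18 for the histone and kinesin list. The histone and kinesin list turned to -1.67 with zeros at the lowest positive value, -0.31 with zeros kept and -0.18 with sets averaged. Those values covered 8, 8 and 7 members, against 5 in the main test, so they do not compare the same genes. The NADH dehydrogenase-like list had 6 members with zeros at the lowest positive value, against 5 in the main test. The NADH dehydrogenase-like list turned to -0.22 on the deposited values, at equal sums and after median centring, -0.50 with zeros at the lowest positive value and -0.0024 with array weights, and ran from -0.061 (without WT replicate 1) to 0.26 on leaving out 1 sample, also below 0 without prors2 replicate 5 (-0.016) or 6 (-0.030); it passed under no alternative, and the cause was not tested. Of the named genes, SECE1 turned to 0.091 and 0.018, LPA19 to 0.077 and 0.0041 and AT3G44050 to 0.093 and 0.0081 on the deposited values and at equal sums, CHLM to 0.061 on the deposited values, and PSB27 and NdhN to -0.19 and -0.21 after median centring. With sets averaged PSB27, SECE1, CHLM, AT3G44050 and AT5G56070 did not pass. AT3G44050 also lost its call without 7 single samples, at log2 differences of -1.01 to -0.69. With zeros at the lowest positive value 9 named genes lost their call although their differences grew, GH9B16 from 1.96 to 5.89, AT4G03150 from 1.84 to 5.88 and AT5G55580 to -4.96 among them, so the spread rose and the difference did not shrink. Signal over background is not known, which limits the dimmest features most.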

Other observations

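The genes in this part were chosen after their values were seen; no explanation for them was tested.

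Several bright or well-known transcripts outside the lists also changed. AT4G17070 went from a deposited 9.83 ± 0.99 (SD, n = 6) to 22.0 ± 3.8, a log2 difference of 1.47 (SE 0.13, limma adjusted p = 2.48e-06), but 0.32 after median centring. CCL (AT3G26740) went from 10.02 ± 0.84 to 18.1 ± 2.0, a log2 difference of 1.13 (SE 0.13, limma adjusted p = 2.54e-05), but 0.02 after median centring. CML30 (AT2G15680), a calmodulin-like protein, rose by 1.59 (SE 0.095, limma adjusted p = 1.47e-07), with a log2 difference of 0.97 after median centring. ATSPS4F (AT4G10120), a sucrose phosphate synthase, rose by 0.80 (SE 0.10, limma adjusted p = 5.50e-05), with a log2 difference of 0.32 after median centring. AT5G58330, a plastid NADP-dependent malate dehydrogenase, fell by 1.38 (SE 0.14, limma adjusted p = 8.70e-06), from 1.75 ± 0.31 to 0.804 ± 0.088. DI21 (AT4G15910), a drought-induced gene, fell by 1.33 (SE 0.20, limma adjusted p = 1.92e-04), but by 0.46 on the deposited values.

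There were 18 features listed at 0 in every WT sample and above 0 in every prors2 sample, and 0 the other way round. A further 71 were at 0 in all 12. WT arrays had more features at 0 in general, 382 ± 10 (SD, n = 6) against 289 ± 20 in prors2. The 18 therefore do not by themselves show genes switched on in prors2. None of the 18 entered the limma test. They include 2 single-gene features. AT3G11150 lay between 0.379 and 0.591 in prors2, with a median of 0.456, and AT1G32220 between 0.0431 and 0.259, with a median of 0.103.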
